A study of Mus musculus with 4 samples.

How the data were processed

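Poly(A) RNA of 4 lung tumour samples, 2 KL and 2 KL25, was sequenced with a strand-specific library kit, per the labels' protocols. Per the labels, reads were trimmed with cutadapt, aligned to GRCm38 and summarised as counts per gene with HTSeq. The aligner, tool versions and strand setting are not given in the sources used here. The submitters' processing notes list both GRCm38 and GRCm39. The values per library that the authors deposited were read as FPKM. Their header names no unit, so this was taken from the values, whose totals were 525970 to 564970 and which were not whole. The authors also deposited, per the file headers, a mean normalized count signal, a log2 fold change with its standard error, a test score, and an unadjusted and an adjusted p-value for each gene. The adjusted p-value in the authors' deposited table is NA for 6653 of 21445 genes.

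Depth was read from the deposited mean normalized count signal. Among genes seen in a single library, 100% of the means were whole multiples of 1 step per library, within 0.01 of a step, which gives that library's size factor. The size factors ranged from 0.823 to 1.30. FPKM were not whole multiples of a step, so counts per gene were not recovered and no counting interval is given. Of the gene names 25 had been turned into dates, and these rows, with 0.117% of the summed FPKM, were left out.

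The design fixed before the data were examined assumed counts and a count-based test. Because the values were read as FPKM, the rule fixed for that case was used: limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(FPKM + 1). It covered genes with a mean of at least 1 FPKM in either group, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate those of low genes. Fold values of means are ratios of FPKM. A list member counts as measured only if it passed this level filter. Of 44 gene lists fixed before the data were examined, the 38 with at least 5 measured members were tested. The test was camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The comparison was KL25 against KL over all 4 libraries without covariates. With 2 mice per group, p-values of single genes rest on the spread between 2 libraries. Camera at the preset correlation compares list members with all other genes. Its p-values therefore do not measure the spread between mice.

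The genes named were Usp25, Usp28 and Stk11, the genes that passed (at most 12 per direction), up to 4 members with the lowest unadjusted p from each list described, and, where fewer than 5 passed in a direction, those with the lowest unadjusted p whose libraries did not overlap, with a mean of at least 5 FPKM in the higher group and a symbol other than a predicted-gene or clone number. Gata6 and other genes taken from the authors' deposited table were chosen after their values were seen. One further gene of this rule is not reported here. Coordinates are from GENCODE annotation of GRCm38, matched by symbol.

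The fit was tested on 20 simulated tables of 12476 genes with the spread of this comparison. It recovered 0.2% of genes changed 2-fold, 3.2% of those changed 4-fold, 63.2% at 16-fold and 70.8% at 64-fold, and called 0.0285% of unchanged genes. Changes were set on the log2(FPKM + 1) scale in random directions. Values were cut at 0, so lowered genes near 0 changed by less than stated. All libraries were simulated with the same spread, without any library standing apart. At the preset correlation, lists shifted by 1 on the log2 scale were called in 100% of cases and other lists in 0%, with genes simulated as independent. Camera with an estimated correlation was not simulated. It rests on the few residual degrees of freedom of these libraries and has little power. The lowest unadjusted p of any list in that test was 0.0728. A list not called with an estimated correlation is therefore not argued against by it. Alternatives covered the pseudocount (0.1 and 5), the filter, scaling, weights, threshold, list test, replicate number and leaving out each library. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other group. A table holding only a title for another pair of groups was not used here.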

Results

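RNA was sequenced from cells labelled CD45-negative that had been prepared from mouse lung tumours 10 weeks after intranasal adenoviral Cre, which recombines floxed alleles in the airway. KL mice carried Cre-dependent tumour alleles, among them floxed Lkb1 (Stk11, a kinase that acts as a tumour suppressor), and KL25 mice also lacked Usp25, a deubiquitinase. Each group had 2 libraries, and the design text gives 2 mice per group. The deposited values were read as FPKM, and the mean normalized count summed over genes was 10577718 per library. Relative depth, read from size factors in the deposited means, was 0.853 and 0.823 in KL25 replicates 1 and 2, and 1.30 and 1.09 in KL replicates 1 and 2. KL replicate 1 stood apart from the other libraries: across genes its correlation with each of them was 0.874 to 0.885, against 0.933 to 0.967 among the others. The others did not separate by group: KL25 replicate 2 was closer to KL replicate 2 (0.967) than to KL25 replicate 1 (0.955). In KL replicate 1, 391 genes lay at least 4-fold above the mean of the other 3 libraries. The same count was 14 in KL replicate 2, 101 in KL25 replicate 1 and 17 in KL25 replicate 2. In every library leukocyte transcripts were abundant. The median of 15 leukocyte genes was 98.8 and 134 FPKM in KL25 replicates 1 and 2, and 166 and 144 FPKM in KL replicates 1 and 2. For 16 pan-epithelial genes chosen after the data were seen it was 30.6 and 14.8 FPKM in KL25, and 10.9 and 8.68 FPKM in KL. Medians of different gene sets do not give cell shares, and the epithelial keratin Krt8 was at 247 to 1067 FPKM. The comparison asked how loss of Usp25 altered the transcriptome of these preparations.

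Usp25 itself was lower in both KL25 libraries than in both KL libraries. Its level was 2.18 ± 0.662 FPKM in KL25 and 27.5 ± 15.4 FPKM in KL (SD, n = 2 each), a 12.6-fold lower mean. The gene lies on chromosome 16 from 77013706 to 77116780 (GRCm38, plus strand), and the remaining signal in KL25 was 2.65 and 1.71 FPKM. On the log2(FPKM + 1) scale the change was -3.07 (SE 0.466), which did not pass in limma (adjusted p = 0.942), while the authors' deposited table gives Usp25 a log2 fold change of -3.70 (SE 0.849) and an adjusted p of 0.0170. Usp28, the paralog of Usp25, was at 1.94 ± 0.369 FPKM in KL25 and 2.96 ± 0.545 FPKM in KL. Stk11 was at 18.8 ± 2.63 FPKM in KL25 and 21.7 ± 3.10 FPKM in KL, and neither gene passed. The 5 measured genes flanking Usp25 on chromosome 16 were not called as a list (median log2 fold change 0.21, camera adjusted p = 0.378), but were called higher without KL replicate 1 (median 0.55, adjusted p = 0.0197), and not with an estimated correlation in that fit (adjusted p = 0.826 with an estimated correlation). Their median was -0.10 without KL replicate 2, 0.34 without KL25 replicate 1 and 0.076 without KL25 replicate 2.

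Genes of the gastric lineage were the most clearly raised group in KL25. Of 16 listed members 12 passed the level filter, which a gene can pass through its higher group alone. All 12 had a positive log2 fold change, with a median of 2.06. In 10 of 12 both KL25 libraries lay above both KL libraries. Chance gives 16.7% for a single gene, and 19.1% of all genes tested did so. Genes of a list can vary together, so such counts are not a test. Of the members left out, at least Muc6 and Cdx2 were negative in the authors' deposited table (-0.735 and -4.13). Their mean normalized counts were 30.1 and 1.92. Tff1, a secreted trefoil peptide of the stomach lining, was at 1303 ± 770 FPKM in KL25 and 88.1 ± 23.9 FPKM in KL, a 14.8-fold higher mean. Gkn1 and Gkn2, which encode gastrokines of the stomach mucosa, had means 36.4-fold and 13.2-fold higher in KL25, and Lgals4, a galectin of the gut epithelium, 5.89-fold higher. KL25 replicate 1 held the higher value of each of these 4 genes, so these folds rest largely on that library. Gkn1 was at 201 and 36.5 FPKM in KL25 replicates 1 and 2, and its SD was close to its mean (119 ± 116 FPKM). Gkn2 was at 645 and 154 FPKM there, against 33.6 and 26.8 FPKM in KL replicates 1 and 2. Lgals4 was at 70.6 and 28.8 FPKM in KL25, against 7.04 and 9.83 FPKM in KL. Tff1 lies on chromosome 17 from 31161395 to 31165277 and Gkn1 on chromosome 6 from 87345650 to 87350942 (GRCm38). The list was called higher by camera (adjusted p = 4.1e-12), but not with an estimated correlation (adjusted p = 0.778 with an estimated correlation). Its median was 1.91 without KL25 replicate 1 and 2.84 without KL25 replicate 2. It was 2.07 without KL replicate 1 and 2.05 without KL replicate 2. Over all genes tested 0 members passed, and 6 passed when adjusted over the list alone.

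**Figure D1:**
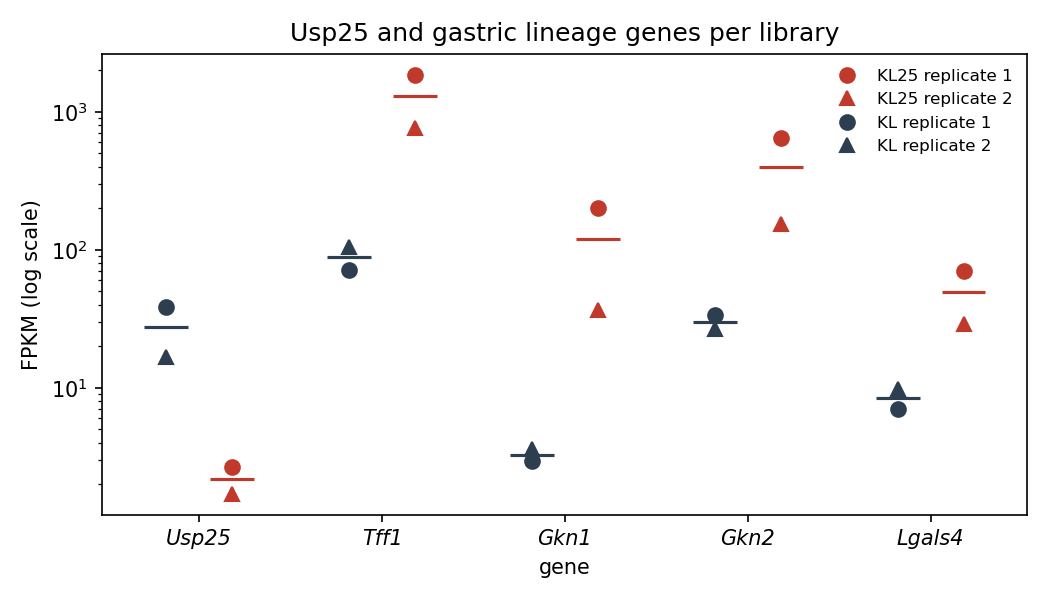
FPKM of Usp25 and of 4 gastric lineage genes in each library, on a log axis, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each group (n = 2). Usp25 lies below both KL libraries in both KL25 libraries, and Tff1, Gkn1, Gkn2 and Lgals4 lie above both KL libraries in both.

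The dedifferentiated tumour cell, MAPK output and mesothelial lists were also higher in KL25. These are levels of whole preparations, and for these lists a different share of cells was not told apart from a change per cell. Lists of alveolar, ciliated and basal cell markers were not called, and the club list was called lower. Among markers of dedifferentiated lung tumour cells 14 of 15 members had a positive log2 fold change (median 1.03, camera adjusted p = 7.6e-06). The simple epithelial keratin Krt18 was at 737 ± 414 FPKM in KL25 and 224 ± 12.7 FPKM in KL, and Krt8 at 724 ± 484 and 249 ± 3.41 FPKM. Areg, a ligand of the epidermal growth factor receptor, was at 580 ± 422 and 191 ± 19.8 FPKM. Their high values lay in KL25 replicate 1, with Krt8 at 1067 FPKM there and 382 FPKM in KL25 replicate 2, and the list median was 0.51 without KL25 replicate 1 and 1.93 without KL25 replicate 2. The 16 pan-epithelial genes, which were not tested as a list, had a median log2 fold change of 0.71. In 9 of them both KL25 libraries lay above both KL libraries, against 16.7% by chance for a single gene and 19.1% of all genes tested. These genes were chosen after the data were seen and can vary together. Transcriptional output genes of MAPK signalling were higher as a list (median log2 fold change 0.50, 14 of 18 positive, adjusted p = 0.0032). Spry2, a feedback inhibitor of the pathway, was at 14.2 ± 2.67 FPKM in KL25 and 7.26 ± 0.106 FPKM in KL, and the transcription factor Etv4 at 7.88 ± 3.06 and 3.60 ± 0.515 FPKM. The mesothelial list was also higher (6 of 6 positive, median log2 fold change 0.85, adjusted p = 0.0019). Msln was at 106 ± 45.0 FPKM in KL25 and 39.3 ± 9.79 FPKM in KL, but the list lay low, at a median of 0.696 to 3.93 FPKM per library. Of the KL25 libraries Msln was higher in replicate 1 (138 against 74.1 FPKM), while Gpm6a, Upk3b and Wt1 were higher in replicate 2. Neither the dedifferentiated, the MAPK nor the mesothelial list was called with an estimated correlation (adjusted p = 0.778 with an estimated correlation for each). The MAPK list was not called without KL25 replicate 1 (median 0.14) or without KL replicate 2 (median 0.44). The dedifferentiated list was not called without KL replicate 2 (median 0.85). The mesothelial list was not called without KL replicate 2 or KL25 replicate 2 (medians 0.88 and 0.32).

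Proliferation and ribosomal protein genes had small positive shifts in KL25. S phase genes had a median log2 fold change of 0.28 (18 of 20 positive, camera adjusted p = 0.0065), with Mcm6, a subunit of the replicative helicase, at 18.7 ± 2.49 FPKM in KL25 and 9.46 ± 2.31 FPKM in KL. G2/M genes had a median of 0.30 (15 of 18 positive, adjusted p = 0.0282), with Ube2c, which acts with the anaphase-promoting complex, at 13.6 ± 5.64 and 6.33 ± 1.86 FPKM. All 22 ribosomal protein genes had a positive log2 fold change (median 0.59, adjusted p = 6.4e-06 for the list). None of the 22 passed, and 0 had an unadjusted p below 0.05. In 18 of them both KL25 libraries lay above both KL libraries, against 16.7% by chance for a single gene and 19.1% of all genes tested. Ribosomal protein genes can vary together by library, so the 18 are not independent. Rps14 was at 2039 ± 414 and 1056 ± 395 FPKM. Ribosomal protein genes lay at their lowest in KL replicate 1, with a list median of 445 FPKM there against 782 FPKM in KL replicate 2, and the median log2 fold change was 0.23 without KL replicate 1 and 0.92 without KL replicate 2. None was called with an estimated correlation (adjusted p = 0.778 with an estimated correlation for each). The S phase list was not called without KL replicate 1 (median 0.13, adjusted p = 0.104) or KL25 replicate 2 (median 0.18, adjusted p = 0.134), and its median was 0.43 without KL replicate 2 (adjusted p = 0.0145) and 0.41 without KL25 replicate 1 (adjusted p = 0.0025). When 1 library was left out the G2/M list was called only without KL25 replicate 1 (median 0.33, adjusted p = 0.0075). Its median was 0.073 without KL25 replicate 2, 0.27 without KL replicate 1 and 0.49 without KL replicate 2 (adjusted p = 0.206, 0.151 and 0.12).

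Genes of class I antigen presentation and general leukocyte genes were lower in KL25. These are levels of whole preparations, and a different share of leukocytes was not told apart from a change per cell. All 17 class I genes had a negative log2 fold change (median -0.67, camera adjusted p = 6.0e-08). In 13 of 17 both KL25 libraries lay below both KL libraries. Chance gives 16.7% for a single gene, and 15.0% of all genes tested did so. Genes of the list can vary together, so the 13 are not independent. H2-Q6, a class I molecule, was at 9.77 ± 6.90 FPKM in KL25 and 37.4 ± 14.5 FPKM in KL, although its reads can be shared with close paralogs. H2-Q8, a class I paralog outside the list and named after its values were seen, went the other way, at 3.51 and 4.63 FPKM in KL25 and 0.197 and 0.141 FPKM in KL. The authors' deposited table gives H2-Q8 a log2 fold change of 4.23 (adjusted p = 0.00261). Psmb9, a subunit of the immunoproteasome, was at 42.6 ± 8.40 and 112 ± 55.7 FPKM, and the peptide transporter subunit Tap2 at 17.8 ± 6.33 and 41.3 ± 14.1 FPKM. The median of the class I list was 150 FPKM in KL replicate 1, 67.8 FPKM in KL replicate 2, and 36.7 and 53.5 FPKM in KL25. Among 15 genes of CD45-positive leukocytes 14 were negative (median -0.70, adjusted p = 6.4e-06), with Cd37 at 29.1 ± 8.21 and 58.0 ± 8.44 FPKM. The class I median was -1.09 without KL replicate 2, and the leukocyte median -0.43 without KL replicate 1. Both lists were called lower without any 1 of the 4 libraries, and neither with an estimated correlation (adjusted p = 0.778 with an estimated correlation for each).

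Interferon, inflammatory and neutrophil genes were lower in KL25 as lists, and their high values lay in KL replicate 1. All 25 type I interferon response genes had a negative log2 fold change (median -1.30, camera adjusted p = 3.0e-10). Cxcl10, an interferon-induced chemokine, was at 466 FPKM in KL replicate 1, 52.9 FPKM in KL replicate 2, and 25.4 and 29.5 FPKM in KL25. NF-kB and inflammatory chemokine genes had a median of -0.85 (19 of 20 negative, adjusted p = 2.5e-04), and the cytokine Tnf was at 305 and 69.2 FPKM in KL replicates 1 and 2, and 43.7 and 27.1 FPKM in KL25. All 10 neutrophil genes were negative (median -1.68, adjusted p = 0.0082). S100a8, an abundant neutrophil protein, was at 19445 FPKM in KL replicate 1, 382 FPKM in KL replicate 2, and 838 and 536 FPKM in KL25. Without KL replicate 1 the interferon list was not called (median -0.15, adjusted p = 0.151), and the NF-kB and neutrophil lists were called higher in KL25 (median 0.27, adjusted p = 0.0287, and median 0.93, adjusted p = 1.1e-04). The NF-kB and neutrophil lists were not called without KL25 replicate 2 (median -0.50, adjusted p = 0.0558, and median -1.36, adjusted p = 0.0855). Without KL replicate 2 the interferon, NF-kB and neutrophil medians were -2.49, -2.13 and -4.09. None was called with an estimated correlation (adjusted p = 0.778 with an estimated correlation for each).

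Club and secretory cell markers and mesenchymal transition genes were the remaining lists called lower. The club list had 9 of 12 members negative (median -0.69, camera adjusted p = 0.0165), and Bpifa1, a secreted airway protein, was at 1653 FPKM in KL replicate 1 and between 24.8 and 32.5 FPKM elsewhere. The club list was not called without KL replicate 1 (median 0.08, adjusted p = 0.561) or KL25 replicate 1 (median -0.45, adjusted p = 0.155), and its median was -1.59 without KL replicate 2. The mesenchymal list had 7 of 9 members negative (median -0.30, adjusted p = 0.0403). Snai1, a repressor of E-cadherin, was at 2.15 ± 0.0147 FPKM in KL25 and 9.05 ± 3.59 FPKM in KL, whereas Sparc, a matrix protein, was at 98.4 ± 40.5 and 44.3 ± 20.1 FPKM. This call was lost without KL replicate 1, KL replicate 2 or KL25 replicate 1 (adjusted p = 0.151, 0.0949 and 0.192), although the medians were then -0.27, -0.48 and -0.40. Its median was -0.56 without KL25 replicate 2, and both lists lost theirs with an estimated correlation (adjusted p = 0.778 with an estimated correlation for each).

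**Figure D2:**
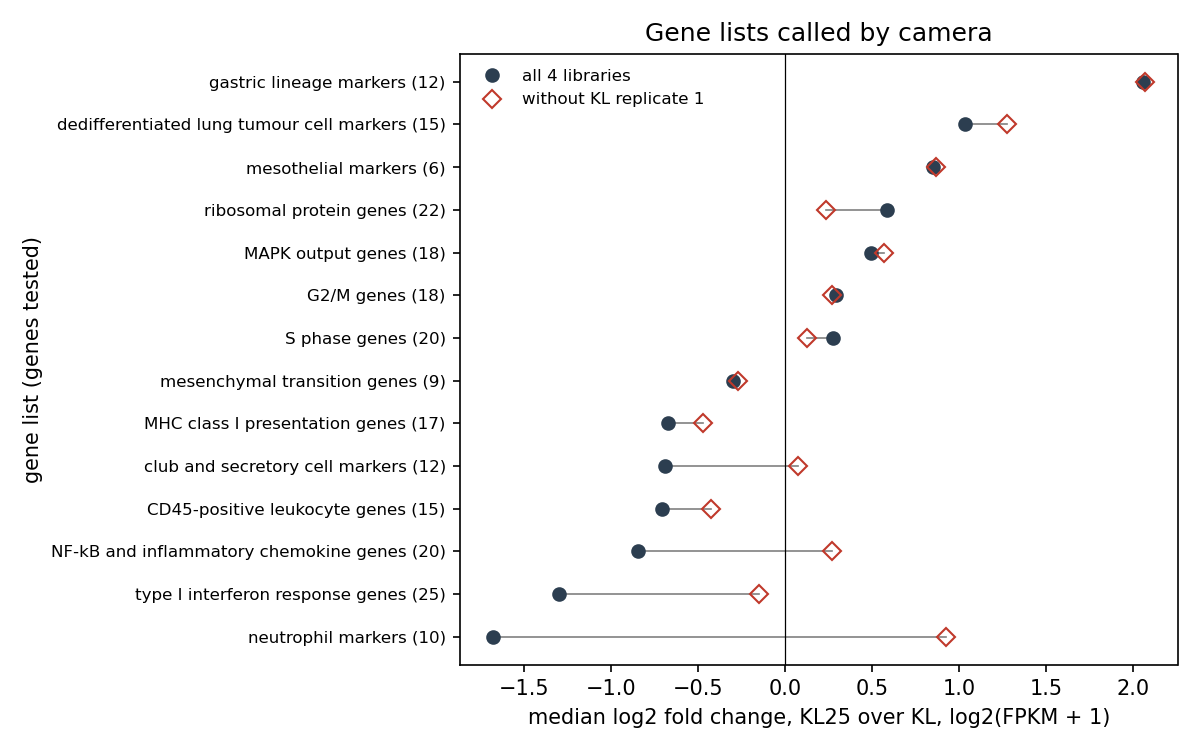
Median log2 fold change of KL25 over KL, on log2(FPKM + 1), for the 14 lists called by camera, with the number of genes tested in brackets, from all 4 libraries (filled circles) and without KL replicate 1 (open diamonds). The neutrophil median moves from -1.68 to 0.93 and the interferon median from -1.30 to -0.15, while the gastric median stays at 2.06 and 2.07.

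Among single genes, 0 of 12476 passed in limma in either direction, with 269 higher and 134 lower at an unadjusted p below 0.05, where chance gives 624. These counts turned on single libraries: they were 279 higher and 296 lower without KL replicate 1, 1244 and 1291 without KL replicate 2, 90 and 46 without KL25 replicate 1, and 320 and 83 without KL25 replicate 2, with 0 genes passing in each of these fits. The authors' deposited table has 348 higher and 529 lower at an unadjusted p below 0.05. With 2 against 2 libraries a two-sided exact permutation test of 1 gene cannot go below p = 0.333. The genes named next had a mean of at least 5 FPKM in the higher group, libraries that did not overlap, and a symbol other than a predicted-gene or clone number. Within these limits the lowest unadjusted p among genes higher in KL25 belonged to Dpcr1, Prap1, Tff1, Ccl7 and Mcpt2, none of which passed. Dpcr1 was at 78.2 ± 25.3 FPKM in KL25 and 10.4 ± 1.56 FPKM in KL, and Mcpt2, a mast cell protease with close paralogs, at 123 ± 61.8 and 19.6 ± 1.66 FPKM. The chemokine Ccl7 was at 12.5 and 13.2 FPKM in KL25, listed at 0 in KL replicate 1 and at 1.73 FPKM in KL replicate 2. Prap1 was at 17.7 and 6.63 FPKM in KL25 and listed at 0 in both KL libraries. Among genes lower in KL25, within the same limits, they were Pira1, Usp25, Snai1, Snord49a and Hist2h2aa1. Pira1, an immunoglobulin-like receptor with close paralogs, was listed at 0 in both KL25 libraries and at 24.4 and 16.5 FPKM in KL. The histone gene Hist2h2aa1, one of a family of near-identical copies, was at 28.0 ± 3.56 FPKM in KL25 and 68.7 ± 5.16 FPKM in KL. The small nucleolar RNA Snord49a was at 1.89 ± 0.111 and 6.45 ± 1.30 FPKM. It rests on few reads, with a mean normalized count of 3.69, and the authors' deposited table gives it an unadjusted p of 0.321. The authors' deposited table holds 13 genes higher and 5 lower in KL25 at an adjusted p below 0.05, among them Tff1, Gkn1, Dpcr1, Gata6, Pira1 and Usp25.

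The other 24 of the 38 lists tested were not called, and 19 of these were called in at least 1 of the fits that left out 1 library. With an estimated correlation 0 lists were called in any of these 4 fits, where still fewer residual degrees of freedom leave almost no power. Alveolar type 2 markers had a median log2 fold change of 0.23 (camera adjusted p = 0.109). They were called higher without KL25 replicate 1 (median 0.43, adjusted p = 0.0111), and their median was 0.070 without KL replicate 1 and 0.077 without KL25 replicate 2. Macrophage markers had a median of -0.05 (adjusted p = 0.272) and were called lower without KL replicate 1 (median -0.38, adjusted p = 0.0036), with medians of 0.26 without KL replicate 2 and 0.20 without KL25 replicate 2. Genes of endoplasmic reticulum stress had a median of 0.17 (adjusted p = 0.0574) and were called higher without KL replicate 1 (median 0.28, adjusted p = 0.0053) or KL25 replicate 2 (median 0.23, adjusted p = 0.0426). Their median was 0.10 without KL25 replicate 1. Hypoxia-inducible genes had a median of 0.11 (adjusted p = 0.0860) and were called higher without KL25 replicate 2 (median 0.46, adjusted p = 4.5e-04), with medians of -0.10 without KL25 replicate 1, 0.21 without KL replicate 1 and 0.045 without KL replicate 2. MHC class II genes, at a median of 0.19 (adjusted p = 0.754), were called lower without KL replicate 1 (median -0.89, adjusted p = 7.4e-05) and higher without KL replicate 2 (median 0.98, adjusted p = 0.0108), with medians of 0.35 without KL25 replicate 1 and -0.13 without KL25 replicate 2. Endothelial markers, at -0.33 (adjusted p = 0.163), were called lower without KL replicate 1 (median -0.84, adjusted p = 3.4e-04) or KL25 replicate 2 (median -0.75, adjusted p = 0.0011), but their median was 0.41 without KL replicate 2 (adjusted p = 0.257) and 0.16 without KL25 replicate 1 (adjusted p = 0.245). A further 6 lists had fewer than 5 members that passed the level filter and were not tested.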

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

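The pseudocounts, absent filter, replicate block, list tests, stricter threshold and left-out libraries were chosen before the data were examined, and the FPKM filter, scalings, weights, robust fit, treat test and authors' test after seeing the data. Across these limma fits 0 genes passed in either direction, and the authors' deposited table has 13 higher and 5 lower and, for Usp25, a log2 fold change of -3.70 (adjusted p = 0.0170); the cause was not tested. Usp25 kept its direction in every fit, from -3.65 to -2.49 without 1 library each and -2.10 with a pseudocount of 5. Of the lists, 7 were higher and 7 lower. With an estimated correlation or with fry both counts were 0. With an estimated correlation few residual degrees of freedom leave little power, so this 0 does not argue against a list. Without a filter 13 were higher. The cause was not tested for fry or for the filter. Leaving out 1 library gave 6 to 11 lists higher and 6 to 8 lower, but not the same lists. Of the 7 lists called lower 2 were also lower without KL replicate 1, where 4 lists not called with all libraries were lower (MHC class II, endothelial, macrophage, and autophagy and lysosome genes, adjusted p = 7.4e-05, 3.4e-04, 0.0036 and 0.0475). Of the 7 lists called higher 5, 3, 6 and 4 were also higher without KL replicate 1, KL replicate 2, KL25 replicate 1 and KL25 replicate 2. The gastric, class I, ribosomal and leukocyte lists were called in each of those fits at the preset correlation. With an estimated correlation, a combination chosen after seeing the data, 0 lists were called without any 1 library, where that test has almost no power. Without KL replicate 1, which holds their high values, the NF-kB, neutrophil and club lists reversed; leaving out 1 library each, their medians ranged from -2.13 to 0.27, -4.09 to 0.93 and -1.59 to 0.076. So did Lcn2 (-5.88 to 0.10), Ltf (-4.16 to 0.63), S100a8 (-4.86 to 0.81) and Cxcr2 (-3.26 to 0.79), none of which passed. Same-numbered libraries share only a number (correlation of deviations across genes 0.152, 2 pairs); with the replicate block 7 lists were higher, 6 lower and 0 genes passed, and Usp25 was at -3.07. DESeq2, voom, TMM, RLE, library-size and CPM-filter alternatives were not run because the tables hold no counts per library, and the other deposited table holds the same values. Size factors ranged from 0.823 to 1.30, and with 2 libraries per group 3.2% of simulated 4-fold changes were recovered.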

Other observations

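Mcpt1, which like Mcpt2 encodes a mast cell protease, and Mcpt8, which encodes a basophil protease, had higher values in both KL25 libraries, although none of the 3 passed the test. Mcpt1 was at 1428 and 592 FPKM in KL25 and 73.8 and 134 FPKM in KL, and Mcpt8 at 164 and 55.8 FPKM against 41.1 and 17.8 FPKM. Among further genes used as mast cell markers Cpa3 was at no more than 0.396 FPKM and Tpsab1 at no more than 0.107 FPKM in any library, and Mcpt4 was listed at 0 and 0.292 FPKM in KL25 and 0.934 and 0.803 FPKM in KL. Kit was at 3.98 and 4.92 FPKM in KL25 and 5.85 and 5.55 FPKM in KL, and Hdc at 39.0 and 23.5 FPKM in KL25 and 287 and 13.5 FPKM in KL. The genes named in this paragraph were chosen after their values were seen. Transcripts of olfactory and vomeronasal receptor genes were listed above 0 for 1071 of 1237 genes in KL replicate 1, 663 in KL25 replicate 1, 239 in KL25 replicate 2 and 156 in KL replicate 2. Of the genes with a positive log2 fold change, 72 are called down in 1 of the authors' deposited tables and 0 in the other. Xndc1 was listed at 0 in both KL25 libraries and at 1.14 and 2.41 FPKM in KL.

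The tests in the paragraphs that follow were all chosen after the results were seen. The lower NF-kB, neutrophil and club lists may rest on KL replicate 1: the list's median log2 value in KL replicate 2 minus that in the higher KL25 library was -0.95, -0.61 and -0.11. For the interferon, class I and leukocyte lists KL replicate 1 alone stays open, since KL replicate 2 lay above the higher KL25 library by 0.047, 0.34 and 0.10, less than the 0.37, 0.53 and 0.43 between the list medians of the KL25 libraries. By member, KL replicate 2 lay above both KL25 libraries in 13 of 25 interferon, 14 of 17 class I and 12 of 15 leukocyte genes, where chance gives 33.3%, which goes against that explanation for the class I and leukocyte lists but comes from 1 library and from genes that are not independent. Greater depth of KL replicate 1 is argued against for the interferon, NF-kB, neutrophil and club lists, since 40 members with a mean of at least 10 FPKM elsewhere had a median log2 excess of 2.45 there, which a depth factor would not produce in FPKM. Genotype stays open, since the lowest adjusted p of these 4 lists with an estimated correlation was 0.778, which neither shows an effect nor excludes it.

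As a hypothesis found and tested on the same data, the gastric list may reflect a change within the epithelial cells and not only a larger share of them. A larger epithelial share as the whole cause is argued against only weakly. The gastric median exceeded that of 16 pan-epithelial genes by 1.34 on the log2 scale (2.06 against 0.71). The permutation p over genes was 1e-05, the smallest that 100000 resamples give. It treats genes as independent and ignores the spread between mice, so it adds no support. The pan-epithelial genes ranged from 0.24 (Marveld3) to 1.63 (Cldn7), and the log2(FPKM + 1) scale understates the change of low ones. KL25 replicate 1 as the only source is also argued against. The list's median log2 value in KL25 replicate 2 lay 2.11 above the higher KL library. The list medians of the KL libraries differed by 0.42. In KL25 replicate 2, 12 of 12 members lay above both KL libraries. A gene can pass the level filter through its higher group alone, so this count adds little. Genotype stays open, since the list's adjusted p with an estimated correlation was 0.778, which neither shows an effect nor excludes it, and so does a larger gastric-type subset of epithelial cells.

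Leukocyte transcripts were abundant although the label is CD45-negative. Lyz2 from alveolar type 2 cells alone is argued against, since the other 14 macrophage genes had a median of at least 106 FPKM in every library. Carried-over CD45-positive cells, which the CD45 beads would have removed if depletion was complete, are a candidate source. The 15 leukocyte genes had a median of at least 98.8 FPKM in every library. The pan-epithelial median was at most 30.6 FPKM, but medians of different gene sets do not give cell shares. A swapped bead fraction cannot be told apart from incomplete depletion, because epithelial genes were present in every library at a level that neither excludes.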
